A study of Mus musculus with 192 samples.

How the data were processed

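The series holds polyA-selected RNA sequencing of mouse hippocampus from zQ175 mice, a knock-in model of Huntington's disease in which an expanded CAG repeat sits in the mouse Htt gene, and from wild-type (WT) mice. Each of the 192 libraries comes from 1 mouse. The deposited table gives expected counts, that is, estimated reads per gene, and the authors made them with RSEM against GRCm38, per the submitters' processing notes. The aligner, the software versions and the annotation release are not given in the sources used here. All values in the deposited table are whole numbers (100 percent), so nothing was rounded, and no normalization had been applied. The table has 41135 features, of which 41128 carry an Ensembl mouse gene identifier. Names, positions and 3' untranslated regions were taken from GENCODE release vM21, in which 40254 of these identifiers were found and 874 were not; the latter were kept under their identifier. The other 7 features are reporter and vector sequences and an additional Htt feature with the suffix HD, which together hold 6.85e-06 percent of all counts; they were left out of the gene tests. Every column was matched to 1 sample through the library name in the labels.

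Groups follow the labels: 3 regimens, 2 genotypes and 4 treatments make 24 groups of 8 mice, 4 of each sex. The labels give no batch and no pairing. Library names hold a number of unstated meaning shared across groups, tried as a block. Libraries sharing it (mean r 0.04 to 0.11) or a replicate label (0.016 to 0.052) correlated slightly.

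Each regimen was fitted on its own with its 64 libraries. Genes with low counts were removed with filterByExpr by group, which left 16575 genes in 2[4]6, 16374 in 6[4]10 and 15852 in 2.6[8]10. Counts were scaled with TMM factors and tested with the quasi-likelihood test of edgeR 4.0.16 in a model of the 8 groups with sex as a covariate. A gene is called changed at a Benjamini-Hochberg adjusted p under 0.05. Changes are on the log2 scale with their standard error (SE), and every adjusted p of a gene is from edgeR unless another tool is named. The contrasts were zQ175 against WT in untreated and in control-siRNA (NTC) mice, NTC against untreated, each active treatment against NTC, both active treatments against each other, and their interaction with genotype. Genotype by sex was tested over untreated and NTC mice together. Differences between regimens were tested in a model of all 192 libraries and 24 groups.

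Levels are CPM (counts scaled by library total) with TMM factors, or log2 CPM with a prior count of 2. Means are given with the standard deviation (SD). Single values per library were compared with exact two-sided permutation tests of 8 against 8 mice over all 12870 splits, whose smallest possible p is 0.000155. The adjusted values are over 24 tests of Htt and 9 tests of the signature score. The signature of a regimen is the set of genes called between its untreated zQ175 and untreated WT mice when those 16 libraries are fitted alone. A library's score is the mean log2 CPM difference from WT NTC mice over these genes, each taken in the direction of the genotype effect, and is given in percent of the mean zQ175 NTC score. No untreated library enters the comparison of active siRNA with NTC.

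Members of 44 lists of pathways and cell types were tested with camera of limma 3.58.1, with a preset correlation of 0.01 and again with an estimated correlation, adjusted over the 44 lists of a comparison. The list counts are given over all genes tested and adjusted over the list alone. The named genes had a mean log2 CPM of at least 1 and the same sign in females and males. For genotype they are the 10 most raised and 10 most lowered by mean log2 change among genes called in the untreated comparison of all 3 regimens. For each siRNA contrast they are the 5 most raised and 5 most lowered among genes called in at least 2 regimens in 1 direction, filled up with the called genes of smallest adjusted p of any 1 regimen. For interactions, sex and differences between regimens they are the up to 5 of smallest adjusted p. Htt is always named, and each list described names up to 4 members of smallest adjusted p. Genes outside this rule are marked where they appear. The rule, the lists, the groups, the tests and the alternatives not marked below were fixed before the data were examined.

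Errors were estimated from the spread between the 8 mice of a group, from which counting noise was not separated. PCR duplicates were not marked by molecular identifiers. The procedure was tested on simulated data made from the 2[4]6 counts with known changes in 16480 genes: of 50 genes per size, 62 percent of those raised 1.25-fold, 80 percent of those raised 1.5-fold and 96 percent of those raised 2-fold were called, and 88 percent of those at 0.5-fold, while 15 unchanged genes were called. For the interaction, 46, 66 and 80 percent of the raised sizes were called. DESeq2 1.42.0 called 68, 80 and 98 percent.

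The alternatives were DESeq2 size factors, no filter on low counts, the DESeq2 Wald test, limma-voom with the library-name number as a block, a replicate block, no sex term, each replicate number left out, other definitions of the signature, library size alone for the Htt levels, and each library left out in turn with limma-trend. Counts under the alternatives are also scaled to 10000 tested genes, those with an adjusted p, since the filters differ; this scaling was chosen after seeing the data. A separate limma-trend fit, to the libraries of each comparison alone, counted calls in 100 splits of them, the real one included. Sex was checked from Xist and Y-linked transcripts, and other tissues from marker lists. The length slope of a library is the slope, over transcript length in log2, of its log2 CPM relative to the mean of its regimen. No library was removed from the main results. Chosen after seeing the data were the alternatives that leave out the 5 libraries that stand apart, the library with a striatal profile or the library high in Skor1, that take a choroid plexus score as a covariate, or that take untreated mice as the reference. R 4.3.3 with data.table (1.17.8), and Python with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 for figures and word counts in 3' untranslated regions, were used.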

Results

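RNA was measured in the hippocampus of 192 mice, 96 zQ175 and 96 WT. The mice were left untreated, or were given a non-targeting small interfering RNA (siRNA) named NTC, an siRNA against full-length HTT named HTT-10150, or 2 siRNAs together, HTT-634 and HTT-486, against HTT1a, a short transcript that ends in the first intron of the gene. In the regimen 2[4]6, mice were treated at 2 months and collected at 6 months of age. In 6[4]10 they were treated at 6 and collected at 10 months, and in 2.6[8]10 they were treated at 2 and at 6 months and collected at 10 months. Each of the 24 groups held 8 mice, 4 per sex. Total counts per library in M (mega) ran from 8.4M to 56M in 2[4]6 (median 27.7M), from 13.4M to 41.3M in 6[4]10 (median 24.5M) and from 13M to 65.7M in 2.6[8]10 (median 16.5M). A separate Htt feature with the suffix HD had reads in 78 of the 96 zQ175 libraries, with at most 11 reads in a library, and in 4 of the 96 WT libraries, with at most 1. Of the 192 libraries, male_4 and female_4 of 6[4]10 zQ175 HTT-10150 had Xist and Y-linked transcripts against their labelled sex, and female_2 of 2.6[8]10 WT NTC had almost none of either.

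The first question was how far each siRNA lowered its target. Htt (ENSMUSG00000029104, GRCm38 chromosome 5, 34761740 to 34912534) was lower with HTT-10150 in all 3 regimens and both genotypes, whereas total Htt with HTT-634 and HTT-486 did not differ by the exact test. In zQ175 mice, Htt stood at 109 ± 37.2 CPM (SD, n = 8) with HTT-10150 and at 146.2 ± 18.5 with NTC in 2[4]6, 25.4 percent lower (exact p = 0.028, adjusted 0.042, 5 of 8 mice below every NTC mouse). In 6[4]10 the levels were 87.4 ± 34.7 and 141.6 ± 14.6 CPM, 38.2 percent lower (exact p = 0.00311, adjusted 0.00746, 7 of 8 mice). For 2.6[8]10 they were 75.2 ± 27.5 and 142.02 ± 12.96 CPM, 47 percent lower (exact p = 0.000155, the smallest possible, adjusted 0.000746, 8 of 8 mice). In WT mice HTT-10150 left Htt 48.3, 32 and 58.4 percent lower in the same order (exact p = 0.000155, 0.00404 and 0.000155). With HTT-634 and HTT-486, Htt was 0.9, 4.4 and 1.4 percent lower than with NTC in zQ175 (exact p = 0.883, 0.332 and 0.726), and in WT it stood at 97.8, 101.8 and 107.1 percent of NTC (exact p = 0.596, 0.757 and 0.0587). The polyA-selected gene counts do not separate HTT1a from full-length Htt, so the target of this pair was not measured. Untreated zQ175 mice had 15.9, 17.5 and 20.8 percent less Htt than untreated WT mice (exact p = 0.000311, 0.000155 and 0.000155). Within the HTT-10150 groups of zQ175 mice the SD was larger than with NTC, and in 2[4]6 the exact p rose to 0.0525 without mouse female_2 of the HTT-10150 group.

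**Figure D1:**
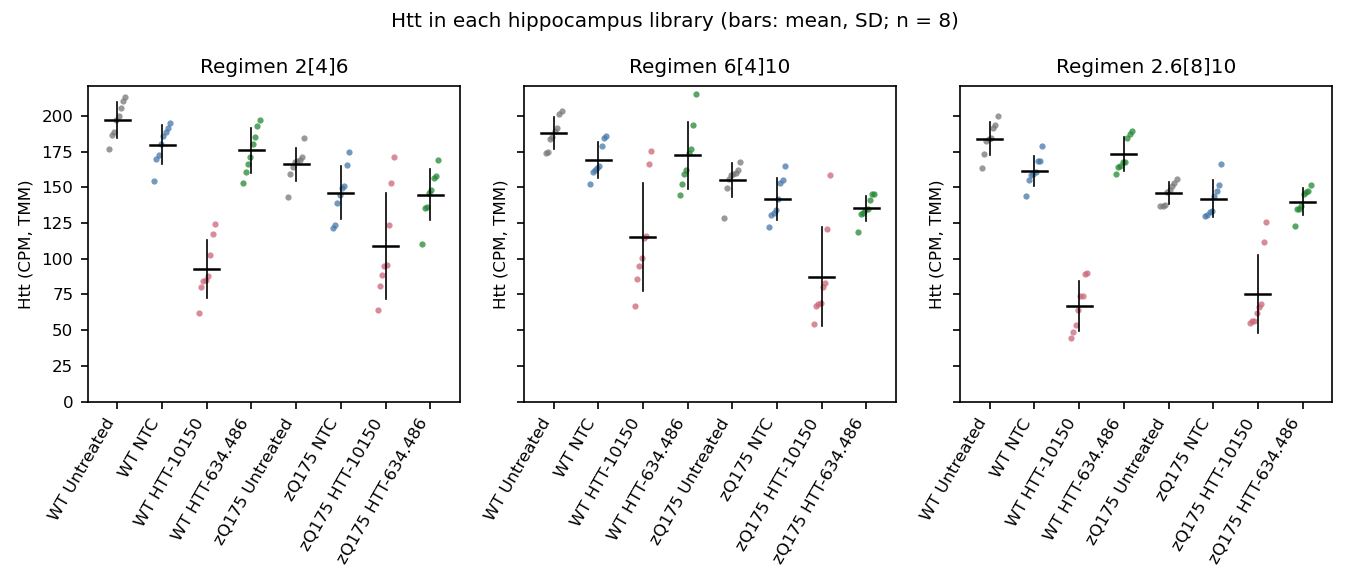
Htt level in CPM (y axis) in each of the 192 libraries, by genotype, treatment and regimen (x axis); points are mice and bars give the mean with the SD (n = 8). The HTT-10150 groups average 67.2 to 115.1 CPM, below the NTC group of the same genotype and regimen in every case.

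Comparing untreated zQ175 with untreated WT mice asked what the knock-in allele alone does. Several genes abundant in hippocampal neurons were lower in zQ175 at both ages. Wfs1 (ENSMUSG00000039474, chromosome 5, 36966104 to 36989205), an endoplasmic reticulum protein abundant in CA1 pyramidal cells, Bok, a BCL-2 family member abundant in hippocampal neurons, Plk5, a brain-expressed polo-like kinase, and C1ql2, a synapse organiser made by granule cells, all fell in the 3 regimens. Raised in all 3 were Onecut1, a developmental transcription factor, Scn9a, a voltage-gated sodium channel, Sstr1, a somatostatin receptor, Trhr, the receptor for thyrotropin-releasing hormone, and Cidea, a lipid droplet protein. Wfs1 fell by 0.95 ± 0.11, 1.14 ± 0.10 and 1.05 ± 0.09 on the log2 scale (SE; 2[4]6, 6[4]10 and 2.6[8]10; adjusted p = 6.7e-08, 1.58e-12 and 9.63e-13), and Bok by 0.72 ± 0.10, 1.05 ± 0.08 and 0.95 ± 0.13. Onecut1 rose by 1.06 ± 0.17, 1.02 ± 0.15 and 1.15 ± 0.20 (adjusted p = 1.41e-05, 1.41e-06 and 4.95e-05), and Cdhr1, a photoreceptor cadherin, by 0.88 ± 0.12, 1.09 ± 0.11 and 1.10 ± 0.09. Among the named genes the most raised was Abhd1 (ENSMUSG00000006638, 1.49 ± 0.17, 1.21 ± 0.21 and 1.33 ± 0.17), which lies on chromosome 5 within 10 Mb of Htt, as do Wfs1 and the lowered Otof (-0.83 ± 0.15, -1.29 ± 0.15 and -1.32 ± 0.23), a calcium sensor of exocytosis. The other genes picked by the rule were Gm16551, B430212C06Rik and Clec1a among those raised and Tnfrsf25, Cldn22, Ighm, Lrrc10b and Pla2g2f among those lowered. Htt itself changed by -0.25 ± 0.11, -0.28 ± 0.13 and -0.34 ± 0.11 in this model, with adjusted p = 0.256, 0.174 and 0.0369.

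The number of genes called was 688 in 2[4]6 (309 raised, 379 lowered), 1890 in 6[4]10 (876 and 1014) and 1762 in 2.6[8]10 (739 and 1023). Most changes were small: the median size of a called change was 0.25 log2 units in each regimen, and 24, 91 and 73 genes changed at least 2-fold. Without replicate 3 the first count was 320, and without replicate 2 the last was 905.

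**Figure D2:**
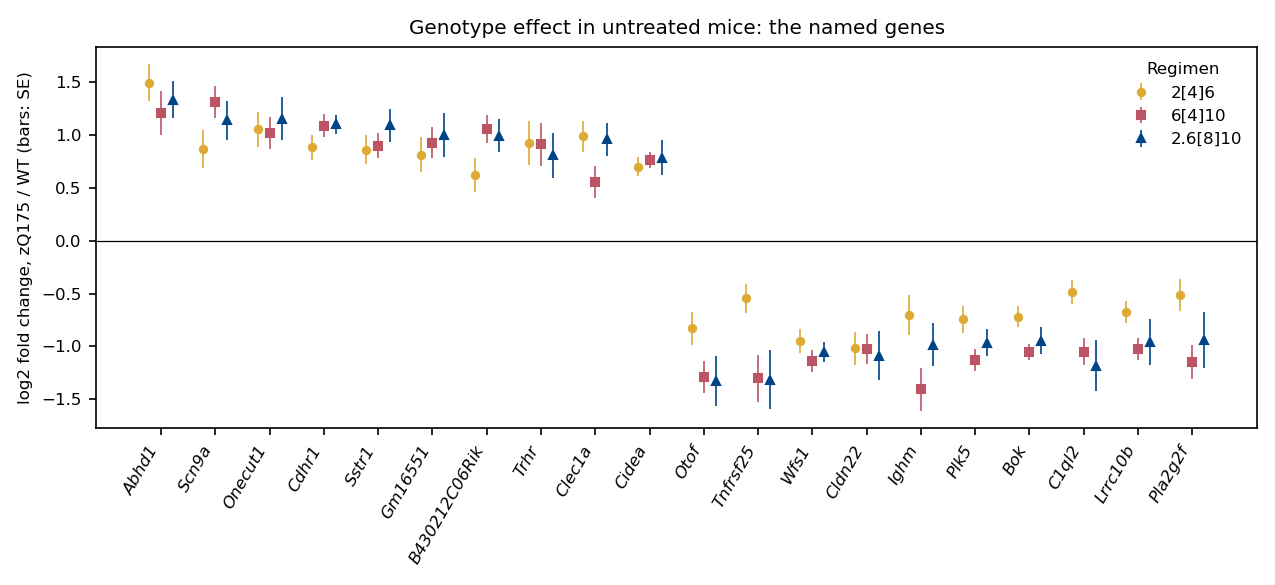
Log2 change between untreated zQ175 and untreated WT mice (y axis) for the 20 named genes (x axis) in the 3 regimens; points are edgeR estimates with the SE (8 mice per group). The 10 raised genes lie above 0 and the 10 lowered genes below 0 in each regimen.

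Sterol synthesis genes fell most broadly in 6[4]10, where 19 of 25 tested members fell and none rose (0 raised; 21 lowered when adjusted over the list alone; camera adjusted p = 0.00972 with an estimated correlation). These included Cyp51 (-0.35 ± 0.05), Hmgcs1 (-0.33 ± 0.04) and Srebf2, the transcription factor that drives it (-0.24 ± 0.04). Of 25 members in 2[4]6, 5 fell (12 adjusted over the list alone; adjusted p = 0.154 with an estimated correlation), and in 2.6[8]10, 10 of 24 (11; adjusted p = 0.16).

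Some developmental transcription factors that are silent in the adult forebrain rose. Of a list of 30, 14 could be tested in 6[4]10, and 7 rose (8 raised when adjusted over the list alone); 12 could be in 2.6[8]10, and 5 rose (8), and 12 in 2[4]6, where 3 rose (3 raised and 1 lowered). The filter keeps a gene that is silent in WT only if zQ175 mice express it, so these shares lean towards rises. Onecut2 rose by 0.85 ± 0.10 in 6[4]10 (adjusted p = 1.52e-09), and Foxd1, a forkhead factor, rose by 1.45 ± 0.33 and 1.32 ± 0.20 at 10 months (adjusted p = 0.00119 and 2.9e-06) but had a change of -0.09 ± 0.27 in 2[4]6. Hoxa2 stood at 0.98 ± 0.19 CPM in untreated zQ175 mice of 6[4]10 and at 0.99 ± 0.33 in those of 2.6[8]10, with every untreated WT mouse at 0.04 or less, and Hoxc4 at 0.67 ± 0.18 and 0.69 ± 0.27 CPM, with untreated WT mice at 0.06 or less.

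Genes of excitatory synapses and of calcium handling fell in 2.6[8]10. There, 13 of 30 tested genes for glutamate receptors and the postsynapse fell and 0 rose (13 lowered and 1 raised when adjusted over the list alone; adjusted p = 0.0253 with an estimated correlation), among them the NMDA receptor subunit Grin2b (-0.44 ± 0.06, adjusted p = 2.8e-07), the kinase subunit Camk2b (-0.38 ± 0.06) and the scaffold Dlg4 (-0.28 ± 0.05). For 6[4]10, 11 of 30 fell (17 lowered and 1 raised when adjusted over the list alone; adjusted p = 0.116 with an estimated correlation). Of 31 calcium genes in 2.6[8]10, 10 fell and 1 rose (13 and 2 adjusted over the list alone; adjusted p = 0.0443 with an estimated correlation), with Itpka, a kinase of dendritic spines (-0.65 ± 0.07, adjusted p = 1.07e-09), the calcium pump Atp2b1 (-0.42 ± 0.06) and hippocalcin, Hpca (-0.50 ± 0.07). In 6[4]10, 11 of them fell and 1 rose (14 and 1; adjusted p = 0.146).

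Some markers of the hippocampal fields fell, without a call of a list once the correlation was estimated. Among 16 dentate granule cell markers, 4 fell in 2[4]6 (7 adjusted over the list alone), 7 in 6[4]10 (8) and 10 in 2.6[8]10 (11), with adjusted p = 0.423, 0.124 and 0.16 with an estimated correlation. Of 16 CA3 and CA2 markers, 8 fell in 6[4]10 (8; adjusted p = 0.0729 with an estimated correlation), including Cdh24 (-0.84 ± 0.11), and of 12 CA1 markers 3, 5 and 4 fell in the 3 regimens (4, 6 and 5; adjusted p = 0.0719, 0.109 and 0.175). Among 19 neuropeptide genes in 6[4]10, 5 fell (5 lowered and 1 raised when adjusted over the list alone; adjusted p = 0.116 with an estimated correlation), with Penk, the enkephalin precursor, at -1.21 ± 0.15 and Chgb, a granin of secretory vesicles, at -0.54 ± 0.05. Of 25 activity-regulated genes in 2[4]6, 5 fell (13 adjusted over the list alone; adjusted p = 0.154 with an estimated correlation), with Arc at -0.75 ± 0.21 (adjusted p = 0.0252) and Egr2 at -1.46 ± 0.41 (adjusted p = 0.0261). Among 16 astrocyte markers of 2.6[8]10, 7 fell and 1 rose (10 and 1; adjusted p = 0.0647 with an estimated correlation), including the glutamate transporter Slc1a2 (-0.41 ± 0.04, adjusted p = 5.14e-10) and glutamine synthetase, Glul (-0.33 ± 0.04). The mismatch repair gene Msh3, a modifier of repeat expansion, rose by 0.24 ± 0.04 in 6[4]10 (adjusted p = 9.52e-05) and by 0.23 ± 0.05 in 2.6[8]10, where 4 of 12 repair genes rose (4; adjusted p = 0.129 with an estimated correlation).

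In NTC mice the same genotype contrast asked whether these differences hold in mice given a control siRNA. It called 867 genes in 2[4]6 (373 raised, 494 lowered), 2411 in 6[4]10 (1078 and 1333) and 1652 in 2.6[8]10 (711 and 941). Abhd1 rose by 1.58 ± 0.18, 1.33 ± 0.21 and 1.41 ± 0.17, Onecut1 by 0.88 ± 0.17, 1.26 ± 0.15 and 1.38 ± 0.21, and Wfs1 fell by 0.89 ± 0.11, 0.89 ± 0.10 and 0.73 ± 0.09. Developmental transcription factors rose, 5 of 14 in 6[4]10 (8 adjusted over the list alone) and 6 of 12 in 2.6[8]10 (7). Sterol genes fell, 16 of 25 in 6[4]10 (19; adjusted p = 0.0407 with an estimated correlation) and 10 of 24 in 2.6[8]10 (16; 0.0772). In the CA3 and CA2 list of 6[4]10, 8 of 16 fell (9; adjusted p = 0.0407), and in the astrocyte list of 2.6[8]10, 11 of 16 fell and 1 rose (11 and 1; adjusted p = 0.044). The glutamate receptor and calcium lists of 2.6[8]10 were not called here (adjusted p = 0.172 and 0.146 with an estimated correlation). Penk fell by 0.75 ± 0.10 in 2[4]6 and by 1.64 ± 0.15 in 6[4]10, and in 2.6[8]10 its change was -1.57 ± 0.55 (adjusted p = 0.0525). Leaving out replicate 1 gave 355 genes in 2[4]6, and leaving out replicate 2 gave 844 in 2.6[8]10.

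**Figure D3:**
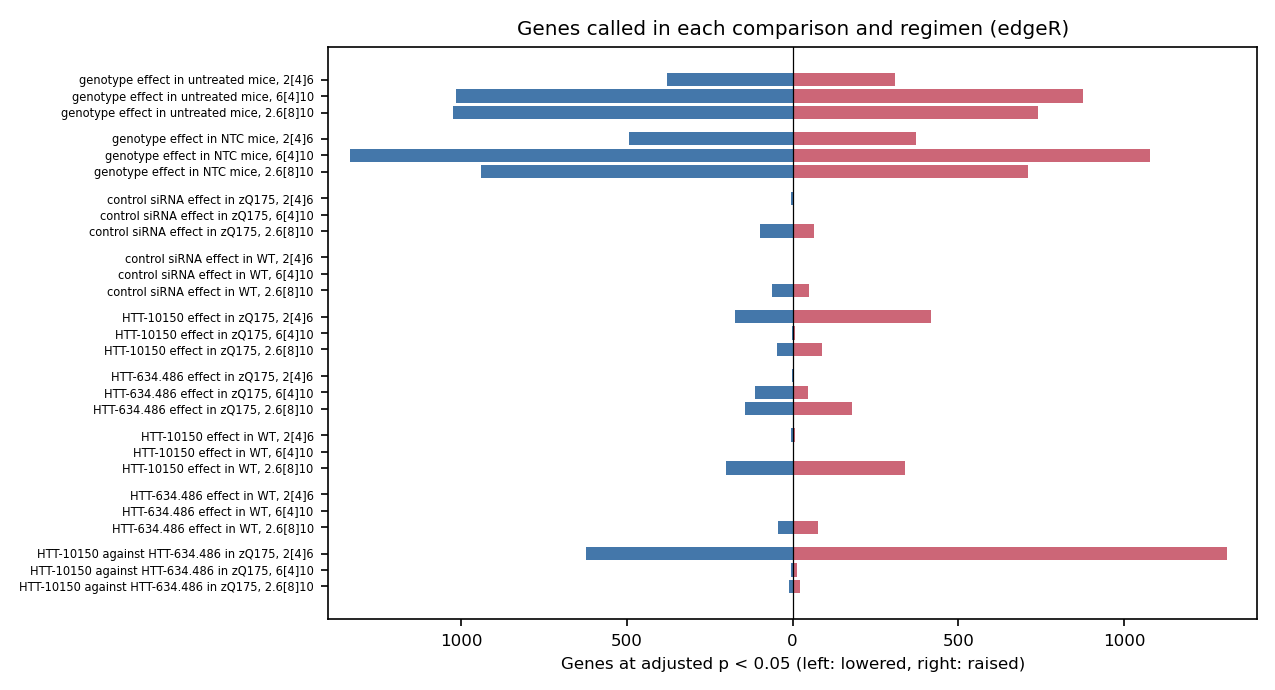
Number of genes called raised or lowered by edgeR at an adjusted p under 0.05 (x axis, bars from 0) for each comparison (y axis) in the 3 regimens, 8 mice per group. The genotype contrasts call 688 to 2411 genes and the siRNA contrasts 0 to 1934.

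NTC against untreated mice measured what the control siRNA and its delivery did. After 2 treatments, in 2.6[8]10, C4b, a complement component, rose in both genotypes, by 0.85 ± 0.14 in zQ175 (adjusted p = 0.000106) and by 0.72 ± 0.14 in WT (adjusted p = 0.00374). In zQ175 mice the microglial receptors C3ar1 (1.14 ± 0.17, adjusted p = 2.01e-05) and Csf3r (0.71 ± 0.12) and the myosin Myo1f (0.73 ± 0.14) rose with it, and so did Cst7 (2.18 ± 0.45, adjusted p = 0.00285) and Clec7a (1.68 ± 0.38, adjusted p = 0.00978), which mark activated microglia. Ado, an enzyme of thiol oxidation, Ssr1, a subunit of the translocon, and Abhd3, a phospholipase, fell in zQ175 by 0.55 ± 0.06, 0.29 ± 0.03 and 0.48 ± 0.05 (adjusted p = 5.65e-09, 8.13e-09 and 8.13e-09), and Ado and Ssr1 also fell in WT, by 0.43 ± 0.06 and 0.25 ± 0.03. Also named were Son (raised), Ddx1 and Slc30a4 (lowered) in zQ175, Trak2, Enpp6, Ube2j2 and Hsbp1 (raised), Lynx1, Pdf and Zfp704 (lowered) in WT.

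The calls of 2.6[8]10 were 63 raised and 98 lowered genes in zQ175, and 48 and 62 in WT. Of 17 activated microglia genes in zQ175, 3 rose (8 raised and 1 lowered when adjusted over the list alone; adjusted p = 0.604 with an estimated correlation). The 18 homeostatic microglia markers went both ways: Trem2 (0.50 ± 0.11) and C1qc (0.44 ± 0.11) rose, and Fcrls (-0.51 ± 0.08, adjusted p = 3.73e-05) and Itgam (-0.44 ± 0.08) fell; 6 rose and 6 fell when adjusted over the list alone, and the list as a whole had adjusted p = 0.995 with an estimated correlation. Of 12 developmental factors, 1 fell (3 adjusted over the list alone; adjusted p = 0.0394 with an estimated correlation). After 1 treatment, 5 genes were called in zQ175 of 2[4]6, all lowered (214 calls with DESeq2); chosen after their values were seen, they were Rgs5 (-0.34 ± 0.07), a pericyte marker, Esyt2 (-0.23), Elovl6 (-0.26), Zfp366 (-1.08) and Mmp23 (-0.91). The other contrasts had 0 calls with edgeR: 612 genes had an unadjusted p under 0.05 in zQ175 of 6[4]10 (2 calls with DESeq2), 614 in WT of 2[4]6 (2 with DESeq2, 2 with limma-voom) and 1244 in WT of 6[4]10 (4 with DESeq2). Without replicate 3 the counts of 2.6[8]10 were 33 and 14, and the count of 5 in 2[4]6 became 495.

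HTT-10150 against NTC in zQ175 mice showed Htt falling together with a rise of microglial transcripts. Lag3 (ENSMUSG00000030124, chromosome 6, 124904361 to 124911705), an immune checkpoint receptor that microglia express, rose by 0.65 ± 0.11, 0.85 ± 0.12 and 1.17 ± 0.12 (adjusted p = 0.000124, 4.26e-05 and 4.35e-10), and Fcrls, a marker of homeostatic microglia, by 0.42 ± 0.09, 0.52 ± 0.09 and 0.83 ± 0.08 (adjusted p = 0.00584, 0.00194 and 7.07e-11). Olfml3, another microglial gene, rose by 0.30 ± 0.08, 0.50 ± 0.09 and 0.61 ± 0.09. Htt fell by 0.43 ± 0.11, 0.69 ± 0.13 and 0.92 ± 0.11 (adjusted p = 0.0244, 0.00542 and 6.16e-08). Nsg1, a neuronal endosome protein, fell in 6[4]10 (-0.34 ± 0.07) and 2.6[8]10 (-0.44 ± 0.10), as did Trak2, an adaptor for mitochondrial transport (-0.27 ± 0.05 and -0.39 ± 0.05). The GTPase Nras fell in 2.6[8]10 (-0.24 ± 0.03). C1qa rose in 6[4]10 (0.52 ± 0.11) and 2.6[8]10 (0.46 ± 0.11), and Mlph in 2[4]6 (0.44 ± 0.12) and 2.6[8]10 (0.65 ± 0.12).

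Of the 18 homeostatic microglia markers, 3 rose in 2[4]6 (7 adjusted over the list alone; adjusted p = 0.458 with an estimated correlation), 3 in 6[4]10 (13; adjusted p = 0.00673) and 6 in 2.6[8]10 (10; adjusted p = 0.0695), where P2ry12 rose by 0.32 ± 0.06 and Siglech by 0.38 ± 0.08. None fell in any regimen (0 lowered). With untreated mice as the reference, the Lag3 change was 0.52, 0.70 and 0.63 and the Fcrls change 0.13, 0.25 and 0.33, with adjusted p = 1, 0.359 and 0.0187 for Fcrls, which was lower in NTC than in untreated mice. Skor1 (ENSMUSG00000022245, chromosome 9, 63138170 to 63148961), a transcriptional corepressor that is nearly silent in WT hippocampus, fell in 2.6[8]10 by 1.28 ± 0.17 (adjusted p = 1.96e-06), from 9.78 ± 1.88 CPM with NTC to 3.99 ± 0.79 with HTT-10150 (n = 8). Its change in 2[4]6 was 2.34 ± 0.59, which 1 mouse carried: female_4 had 16.07 CPM and every other zQ175 mouse of that regimen 0.57 or less.

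Vessel genes moved as well in 2[4]6. Of 13 endothelial markers, 9 rose and 0 fell (10 adjusted over the list alone; adjusted p = 0.0212 with an estimated correlation), with the VEGF receptors Flt1 (0.65 ± 0.08, adjusted p = 3.43e-07) and Kdr (0.41 ± 0.07), the cadherin Cdh5 (0.54 ± 0.09) and the efflux pump Abcb1a (0.46 ± 0.09). Of 10 pericyte and smooth muscle markers, 4 rose (5; adjusted p = 0.16 with an estimated correlation), including Rgs5 (0.43 ± 0.07). Of 33 ribosomal protein genes, 15 fell (29; adjusted p = 0.207 with an estimated correlation). In the later regimens Flt1 had changes of -0.15 ± 0.08 and -0.11 ± 0.08 (adjusted p = 0.746 and 0.669), and against untreated mice of 2[4]6 its change was 0.31 (adjusted p = 0.266).

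The calls numbered 591 in 2[4]6 (416 raised, the rest lowered), 11 in 6[4]10 (8 and 3) and 138 in 2.6[8]10 (90 and 48). The count of 2[4]6 was 20 without replicate 4, 1 with untreated mice as the reference and 29 with each library's length slope as a covariate, and by limma-trend it moved from 580 with all libraries to 199 or fewer without NTC mouse male_1 or male_4. For 6[4]10, where 2 mice of the treated group had sex transcripts against their label, Xist was among the calls (5.42), and 6 genes were called without these mice.

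HTT-634 with HTT-486 against NTC in zQ175 mice left total Htt where it was (-0.01 ± 0.11, -0.07 ± 0.13 and -0.02 ± 0.11) and moved several genes against the genotype effect. Bok and Cldn22, which were low in zQ175, rose: Bok by 0.36 ± 0.08 in 6[4]10 and 0.65 ± 0.13 in 2.6[8]10 (adjusted p = 0.0112 and 0.00169), and Cldn22, a claudin, by 0.69 ± 0.15 and 1.22 ± 0.24 (adjusted p = 0.0149 and 0.00141). Lag3 rose in all 3 regimens (0.51 ± 0.11, 0.66 ± 0.12 and 1.11 ± 0.12; adjusted p = 0.0444, 0.00248 and 4.99e-09), and C1qa, a complement component made by microglia, rose by 0.54 ± 0.11 in 6[4]10 and 0.57 ± 0.11 in 2.6[8]10. Csf1r, the receptor that microglia need for survival, fell in all 3 (-0.24 ± 0.05, -0.25 ± 0.05 and -0.36 ± 0.06; adjusted p = 0.0444, 0.0112 and 0.000191). Col11a1, a collagen, rose and 2610002M06Rik, Ppl, Magt1 and Fgf1 fell in both 10-month regimens; 2610002M06Rik fell by 0.47 ± 0.07 and 0.51 ± 0.07, and Ppl in 2.6[8]10 turned to 0.04 against untreated mice. Skor1 fell in 2.6[8]10 by 1.54 ± 0.18 (adjusted p = 1.63e-08), to 3.37 ± 1.39 CPM.

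Among 18 microglia markers of 2.6[8]10, C1qa and Tyrobp (0.43 ± 0.12) rose while Csf1r and Tmem119 (-0.28 ± 0.08) fell. In 6[4]10, 2 of 16 activated microglia genes rose (7 adjusted over the list alone; adjusted p = 0.434 with an estimated correlation), Clec7a (1.46 ± 0.30) and Lyz2 (1.11 ± 0.25), and 2 of 13 complement genes, C1qa and C1qb (6; adjusted p = 0.584). In the same contrast the mean of 15 choroid plexus genes, which mark neighbouring tissue, was 2.72 log2 CPM against 1.27 with NTC. Of 16 astrocyte markers in 2.6[8]10, 2 rose (7; adjusted p = 0.329 with an estimated correlation). The calls numbered 5 in 2[4]6 (4 raised, 1 lowered), 157 in 6[4]10 (45 and 112) and 323 in 2.6[8]10 (179 raised). Beyond Lag3 and Csf1r, those of 2[4]6 were, chosen after their values were seen, Abhd3 (0.30), Slain1 (0.35) and Clmp (0.41). With untreated mice as the reference the counts were 1091, 638 and 777, and the change of Bok in 2.6[8]10 was 0.20 (adjusted p = 0.432). Without replicate 2 the count of 6[4]10 was 12, and without replicate 3 that of 2.6[8]10 was 71.

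**Figure D4:**
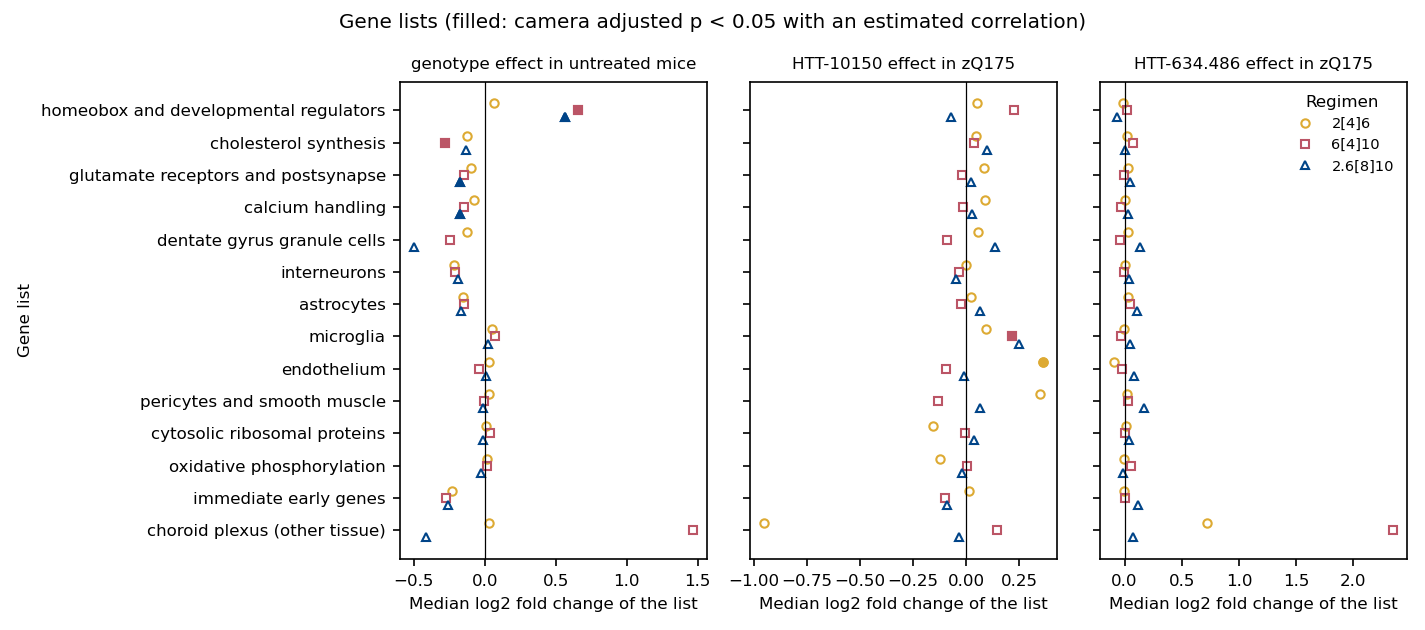
Median log2 change (x axis) of selected gene lists (y axis) in the 3 regimens for genotype in untreated mice and for each active treatment in zQ175 mice, 8 mice per group; filled points have a camera adjusted p under 0.05 with an estimated correlation. The sterol list lies at -0.282 in untreated zQ175 mice of 6[4]10 and the microglia list at 0.248 with HTT-10150 in zQ175 mice of 2.6[8]10.

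In WT mice HTT-10150 raised several microglial genes that were also called in zQ175: Lag3 by 0.73 ± 0.11, 0.65 ± 0.12 and 1.12 ± 0.12 (adjusted p = 8.69e-05, 0.0162 and 3.7e-09), and Fcrls, Olfml3 and Mlph in 2[4]6 (0.49 ± 0.09, 0.44 ± 0.08 and 0.71 ± 0.12) and 2.6[8]10 (0.70 ± 0.08, 0.66 ± 0.10 and 0.41 ± 0.12). Abca8a, a lipid transporter, rose in the same regimens (0.53 ± 0.09 and 0.53 ± 0.08). Htt fell by 0.95 ± 0.12 and 1.27 ± 0.11 in 2[4]6 and 2.6[8]10 (adjusted p = 2.84e-07 and 6.03e-12) and had a change of -0.55 ± 0.13 in 6[4]10 (adjusted p = 0.16). Nsg1, Cdkl2, Api5 and Wdr1 fell in 2[4]6 and 2.6[8]10. Of 18 microglia markers, 2 rose in 2[4]6 (12 adjusted over the list alone; adjusted p = 0.00156 with an estimated correlation), 0 in 6[4]10 (6; 0.863) and 11 in 2.6[8]10 (15; adjusted p = 0.0152). Striatal identity genes rose in 2.6[8]10, 19 of 21 (19; adjusted p = 0.967 with an estimated correlation). There, mouse female_1 had a mean of 9.1 log2 CPM over these genes while the group means elsewhere ran from 4.01 to 4.42, and without it 264 genes were called instead of 540 (339 raised, 201 lowered). The counts of the other regimens were 11 (6 and 5) and 3; the latter were Lag3, Abhd3 (0.33) and, chosen after its values were seen, Cort (0.65).

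With HTT-634 and HTT-486, WT mice showed a rise of Lag3 in 6[4]10 (0.73 ± 0.12, adjusted p = 0.00369) and 2.6[8]10 (0.87 ± 0.12, adjusted p = 9.76e-06) and of Abhd3 in all 3 regimens (0.25 ± 0.05, 0.27 ± 0.05 and 0.38 ± 0.05). Zfp704, Ado and Pdf rose in 2.6[8]10 (0.32 ± 0.04, 0.43 ± 0.06 and 0.63 ± 0.09). These and Abhd3 were lower in NTC than in untreated mice, and against untreated mice the changes of Abhd3 and Ado there were 0.12 and 0.001. Bnip3l, Pigs, Ube2g2, Trak2 and Nras fell in 2.6[8]10, Nras by 0.17 ± 0.03, and Trak2 turned to 0.05 against untreated mice. The calls numbered 2 in 2[4]6, which were Abhd3 and, chosen after its values were seen, Asb16 (0.46), 4 in 6[4]10, where Gabrr2 (1.39) and Fam234a (0.43) came with Lag3 and Abhd3, and 119 in 2.6[8]10 (76 raised, 43 lowered). Against untreated mice 27 genes were called in 2.6[8]10.

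The direct contrast of both active treatments in zQ175 mice asked where they differ. Htt was lower with HTT-10150 in all 3 regimens (-0.42 ± 0.11, -0.62 ± 0.13 and -0.90 ± 0.11; adjusted p = 0.0105, 0.0189 and 3.93e-07). Homeostatic microglia genes were higher with HTT-10150: Fcrls by 0.42 ± 0.09, 0.59 ± 0.09 and 0.71 ± 0.08 (adjusted p = 0.00143, 0.000231 and 1.63e-08), Olfml3 by 0.31 ± 0.08, 0.53 ± 0.09 and 0.56 ± 0.10, Csf1r by 0.26 ± 0.05 and 0.29 ± 0.05 in 2[4]6 and 6[4]10, and Tmem119 by 0.20 ± 0.05 and 0.35 ± 0.08 in 2[4]6 and 2.6[8]10. Pax2, a developmental transcription factor, was higher with HTT-10150 by 0.99 ± 0.21 in 6[4]10 and 1.15 ± 0.22 in 2.6[8]10 (adjusted p = 0.0176 and 0.00298), where the levels were 6.29 ± 1.49 and 2.86 ± 1.63 CPM (n = 8). Its call in 2[4]6 rests on mouse female_4 of the HTT-10150 group at 18.44 CPM. Il33, a cytokine, Pde8a, a phosphodiesterase, Scd1, a fatty acid desaturase, and Nsg1 were lower, Il33 by -0.42 ± 0.10 in 2[4]6 and -0.43 ± 0.09 in 2.6[8]10. The microglia list was higher with HTT-10150 in 6[4]10, 3 of 18 raised (10 adjusted over the list alone; adjusted p = 0.0349 with an estimated correlation), and in 2.6[8]10, 5 raised (10; 0.0568).

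The direct contrast called 1934 genes in 2[4]6 (1311 raised, 623 lowered), and 19 (13 and 6) and 33 (22 and 11) in the later regimens. Endothelial markers were higher with HTT-10150, 11 of 13 (12 adjusted over the list alone; adjusted p = 0.00938 with an estimated correlation), Flt1 by 0.84 ± 0.08. Mean length slopes were 0.0243 with HTT-10150, 0.0246 untreated, -0.0308 with HTT-634.486 and -0.0274 with NTC. Of 20 myelin genes 13 were lower (18; adjusted p = 0.47 with an estimated correlation), such as Mbp (-0.40 ± 0.09), and of 33 ribosomal protein genes 21 (30; adjusted p = 0.373). The thyroid hormone and transthyretin list of 6[4]10 was lower by its test (adjusted p = 0.0278 with an estimated correlation) with 0 of 11 members called by edgeR, 1 adjusted over the list alone. The count of 2[4]6 fell to 78.9 calls per 10000 genes without replicate 3, from 1166.8, and was 848 instead of 2070 by limma-trend without HTT-634.486 mouse male_3.

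The score over each regimen's untreated genotype signature (529, 2326 and 2242 genes) asked how far treated zQ175 mice moved towards WT. With HTT-634 and HTT-486 the zQ175 mice scored 69.1 ± 7.9 percent of the NTC mean in 2[4]6 (SD, n = 8; exact p = 0.000311, adjusted 0.0014, 7 of 8 mice below every NTC mouse) and 63.8 ± 14.8 percent in 2.6[8]10 (exact p = 0.000155, the smallest possible, adjusted 0.0014, 8 of 8), and 88.2 ± 10.2 percent in 6[4]10 (exact p = 0.0301, adjusted 0.0543, 5 of 8). With HTT-10150 they scored 87.1 ± 31.3, 102.1 ± 23.8 and 82 ± 14.5 percent (exact p = 0.321, 0.863 and 0.0129; adjusted 0.361, 0.863 and 0.0387), and the last lost its call without replicate 2, 3 or 4. With a signature from other untreated mice, HTT-634.486 gave 73.7 and HTT-10150 71.2 percent in 2[4]6 (adjusted exact p = 0.062 and 0.0995). Without mouse female_4, which scored 160.8 percent, the HTT-10150 mean of 2[4]6 was 76.5 percent (exact p = 0.00389 before adjustment, 7 against 8 mice), and without mouse male_2, at 154.7 percent, that of 6[4]10 was 94.6 percent (exact p = 0.336). The direct treatment difference had adjusted p = 0.0956, 0.173 and 0.0543. Untreated mice set the signature, so their scores lean outward. In zQ175 they were 108.7 and 95.4 percent in 2[4]6 and 6[4]10 and 0.279 in log2 (NTC 0.242) in 2.6[8]10. In WT they were -9.8, -9.9 and -10.1 percent.

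Of 138 signature genes called with HTT-634 and HTT-486 in 2.6[8]10, all but 5 moved against the genotype effect. In 6[4]10, 29 moved against it and 4 along it. With HTT-10150, 32 moved against and 9 along in 2.6[8]10, 1 and 4 in 6[4]10, and 19 and 5 in 2[4]6. Across signature genes, which are not independent replicates, the Spearman correlation between the genotype effect and the effect of HTT-634 and HTT-486 was -0.70, -0.30 and -0.64, and with HTT-10150 -0.28, 0.04 and -0.40; across all genes it was -0.23, -0.06 and -0.29, and -0.09, 0.03 and -0.20. Both treatments in 2.6[8]10 raised 56 genes in common where independent calls would share 1.02, and lowered 19 where they would share 0.436. The contrasts share their NTC mice. In a fit to these 3 groups alone the shared counts were 123 and 29, and with the NTC mice split into groups of 4 they had medians of 24.5 and 3.

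**Figure D5:**
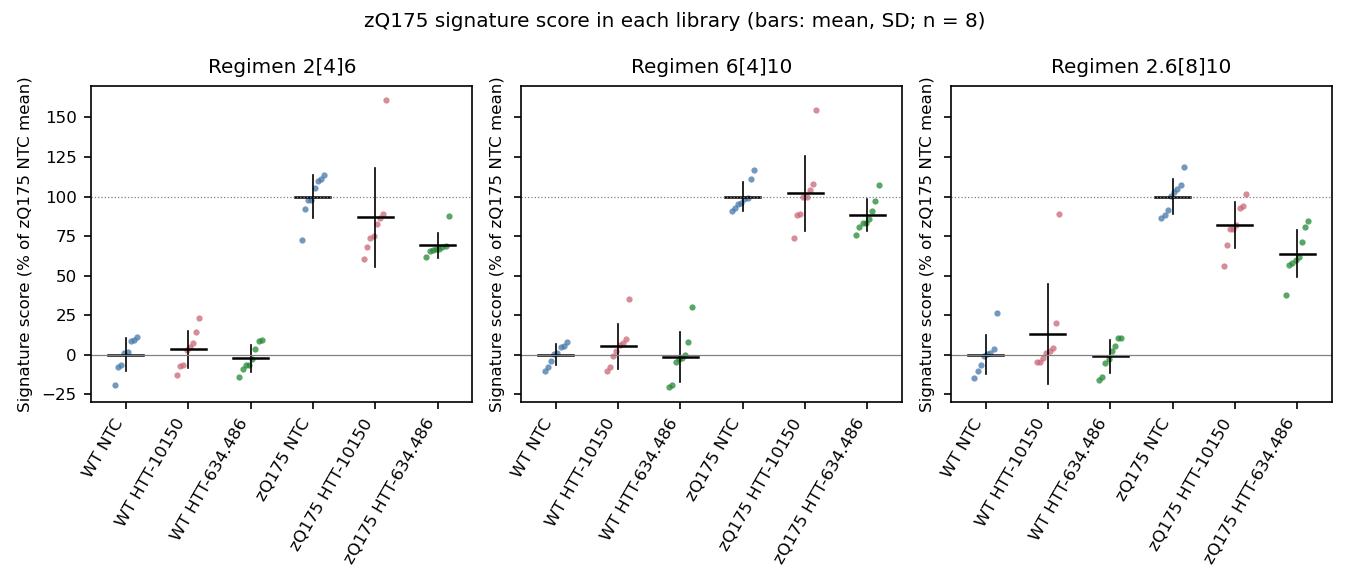
Signature score in percent of the mean of zQ175 NTC mice (y axis) in each library by genotype, treatment and regimen (x axis); points are mice and bars give the mean with the SD (n = 8). With HTT-634 and HTT-486 the zQ175 means are 69.1, 88.2 and 63.8 percent.

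Interaction tests asked whether an siRNA acted differently in zQ175 and WT mice. For HTT-10150, edgeR called 0 genes in 2[4]6 and in 6[4]10 (2191 and 811 at an unadjusted p under 0.05) and 2 in 2.6[8]10, Skor1 (-2.15 ± 0.40, adjusted p = 0.00984) and, chosen after its values were seen, Frem3 (1.54, adjusted p = 0.00484), an extracellular matrix protein. For HTT-634 and HTT-486 it called 0, 0 and 1 genes (452 and 1013 at an unadjusted p under 0.05), the 1 being Frem3 (1.42, adjusted p = 0.0383). No interaction was run with DESeq2. Genotype by sex called 0 genes in 2[4]6 (1680 at an unadjusted p under 0.05), 3 in 6[4]10 and 955 in 2.6[8]10 (110 raised, 845 lowered, as females minus males). Those of 6[4]10 were the clock genes Dbp (0.73 ± 0.13, adjusted p = 0.00917) and Nr1d1 (0.36 ± 0.07) and Garem2 (0.50 ± 0.09). The named genes of 2.6[8]10 were Sulf1, 1500015O10Rik, F5, Ephx1 and Kcnj13, with F5 and Kcnj13 in the choroid plexus list; among untreated mice of that regimen, 3 of 4 WT females and 3 of 4 zQ175 males had high choroid plexus transcripts.

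Between regimens, the genotype effect was larger at 10 than at 6 months for Skor1, by 5.18 ± 0.80 (adjusted p = 1.77e-05) in 6[4]10 and 4.93 ± 0.82 (adjusted p = 0.000158) in 2.6[8]10, relative to 2[4]6, and for Pax2 by 2.87 ± 0.56 in 6[4]10. Skor1 stood at 0.36 ± 0.08 CPM in untreated zQ175 mice at 6 months and at 13.15 ± 4.48 and 13.9 ± 3.25 CPM at 10 months (n = 8), with untreated WT means of 0.15 to 0.22. Rprm (-0.66 ± 0.15) and Mvd, a sterol enzyme (-0.53 ± 0.12), changed the other way. There were 8 genes called in all for 6[4]10 and 23 for 2.6[8]10, the latter with Ago3 (-0.42 ± 0.08), Zbtb20 (-0.65 ± 0.13), Hebp1 and Lyrm7. Both sets collected at 10 months differed in 0 genes in their genotype effect (edgeR; 564 at an unadjusted p under 0.05). Their untreated WT mice nevertheless differed in 677 genes and their untreated zQ175 mice in 453, led by Ndufc2 (1.11 ± 0.11 and 0.89 ± 0.11), so regimen and set cannot be told apart. The HTT-10150 effect differed in 40 genes between 6[4]10 and 2[4]6, with Flt1 (-0.81 ± 0.11, adjusted p = 5.39e-07), Rgs5, Cxcl12 and Podxl lower and Xist higher (5.82), in 170 between 2.6[8]10 and 2[4]6, with Skor1 (-3.72 ± 0.51, carried by mouse female_4 of 2[4]6), Flt1 (-0.76 ± 0.11), Rgs5, Itga6 and Jmjd1c, and in 5 between the 10-month sets: Xist, Eif2s3y, Ddx3y, Abhd3 (0.34 ± 0.07) and, chosen after its values were seen, Twist1 (-1.53). The effect of HTT-634 and HTT-486 differed in 0 genes in each pair (edgeR; 692, 421 and 618 at an unadjusted p under 0.05).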

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

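Chosen only after the result was seen were the tests on the injection with any siRNA, on low endothelial transcripts in the NTC mice and on more vessel tissue, the tests without single mice, and the counts over other splits of the libraries.

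Skor1, a neuronal corepressor, and Pax2, a transcription factor of early development, were among the genes whose genotype effect differed between ages, Pax2 in 6[4]10 only. The test of the difference between regimens called 8 genes for genotype in untreated mice between 6[4]10 and 2[4]6, and 23 between 2.6[8]10 and 2[4]6. Skor1 differed by 5.18 ± 0.80 and 4.93 ± 0.82, and every untreated zQ175 mouse collected at 10 months had at least 7.41 CPM against at most 0.48 in those collected at 6 months. Age and animal set change together here, so the design does not separate them. The HTT-10150 effect differed in 40 genes between 6[4]10 and 2[4]6, in 170 between 2.6[8]10 and 2[4]6, and in 5 between the 10-month sets. Flt1, an endothelial gene, was called in the first pair of contrasts. Skor1 led 2.6[8]10 minus 2[4]6, but its change in 2[4]6 turned from 2.34 to -0.81 without mouse female_4. In the last, Xist, Eif2s3y and Ddx3y are sex-linked, and 2 mice of 6[4]10 zQ175 HTT-10150 had Xist and Y-linked transcripts against their label (male_4 with Xist at 9.66 log2 CPM, female_4 at 0.93). Without the 5 libraries that stand apart, chosen after seeing the data, these counts were 7, 10, 24, 218 and 1, in the order genotype, genotype, then HTT-10150.

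Interaction tests differed between genotypes in 2 genes for HTT-10150 in 2.6[8]10 (Frem3 and Skor1) and in 1 for HTT-634 and HTT-486 (Frem3). Skor1 stood at 9.78 ± 1.88 CPM with NTC and 3.99 ± 0.79 with HTT-10150 in zQ175, while every WT group of that regimen averaged 0.19 to 0.38. The genotype effect differed between the sexes in 3 genes of 6[4]10 (Dbp, Nr1d1 and Garem2) and in 955 of 2.6[8]10, which were led by the choroid plexus genes F5 and Kcnj13. Choroid plexus genes averaged over 5 log2 CPM in 3 of 4 untreated WT females (6.14, 5.43 and 6.52) and 3 of 4 untreated zQ175 males (5.27, 5.88 and 6.51) of 2.6[8]10. The other untreated mice of that regimen had at most 1.79.

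Single mice lay far from the other 7 of their group in 27 of 138 combinations of group and measure, where chance gives about 1 in 20. For the signature score in percent of the zQ175 NTC mean, these were 160.8 (2[4]6 zQ175 HTT-10150 female_4), 87.9 (2[4]6 zQ175 HTT-634.486 female_1), 154.7 (6[4]10 zQ175 HTT-10150 male_2), 35.1 (6[4]10 WT HTT-10150 male_3), 89.1 (2.6[8]10 WT HTT-10150 female_1) and 26.3 (2.6[8]10 WT NTC female_3). For Htt it was 128.2 CPM, the lowest untreated zQ175 mouse of 6[4]10, male_2. For total counts they were 21.1M (2.6[8]10 WT HTT-10150 male_2), 29.3M (2.6[8]10 zQ175 HTT-10150 male_2) and 65.7M (2.6[8]10 zQ175 untreated female_2).

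Marker lists were compared in the same way. The mean log2 CPM of choroid plexus genes was high in 2[4]6 zQ175 HTT-10150 male_1 (5.53), in 6[4]10 zQ175 HTT-10150 male_3 (5.16), zQ175 NTC male_4 (5.1), WT untreated male_3 (4.58), WT HTT-634.486 female_4 (4) and WT NTC male_3 (4.54), and in 2.6[8]10 WT NTC female_3 (6.98), WT HTT-634.486 male_4 (5.55), zQ175 NTC male_2 (5.86) and zQ175 HTT-10150 female_3 (5.61). The mean of striatal genes was high in 2.6[8]10 WT HTT-10150 female_1 (9.1), 6[4]10 WT HTT-634.486 female_4 (5.45) and WT NTC female_4 (4.65), and 2.6[8]10 zQ175 NTC female_3 (4.14). The mean of endothelial genes was low in 2[4]6 zQ175 HTT-10150 male_1 (4.36) and zQ175 NTC female_4 (3.96) and high in 2.6[8]10 WT NTC female_3 (4.86). In 2[4]6 zQ175 untreated female_1, 77 reads fell on the EGFP feature and 5 on the vector feature of an adeno-associated virus, which no comparison used.

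Genes lowered by the control siRNA in WT mice of 2.6[8]10, 62 in number, were weighed first. Of these, 57 were lower in zQ175 too, and 32 were called there. The effect of injection with any siRNA is argued against, since against untreated zQ175 mice their median change was -0.049 with HTT-10150 and -0.044 with HTT-634 and HTT-486 but -0.243 with NTC (quartiles -0.413 and -0.109). Choroid plexus in some libraries is argued against as well: with the choroid plexus score as a covariate, 60 of the 62 were still called. A sequence match between the siRNA and messenger RNAs stays open and may account for part of the list: the 7-base word in 3' untranslated regions that went most with lower expression in WT, TACGATT, ranked 1 of 16286 in zQ175 (statistic -12.06). It occurs in 12 of 56 lowered genes that could be searched, and in 2 percent of all genes; the sequence of the siRNA was not in the sources used here.

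Endothelial genes raised by HTT-10150 in zQ175 mice of 2[4]6 were weighed second; their median change was 0.363 (quartiles 0.188 and 0.413) and 0.027 in WT. A trend with transcript length is argued against as the whole cause, as the median was 0.34 with the length slope as a covariate. Yet 3 members were then called instead of 9, and 29 genes in all instead of 591. Low endothelial transcripts in the NTC mice may explain much of it, since the median against untreated mice was 0.131 (quartiles 0.081 and 0.181) with 0 members called (edgeR; DESeq2 was not run on this reference). More vessel tissue in the libraries stays open, since pericyte and smooth muscle markers rose by a median of 0.348. The difference between the genotypes had a median of 0.336, with 8 of 13 members at an unadjusted p under 0.05 and no gene called (0 by edgeR, 2191 genes at an unadjusted p under 0.05), and a biological effect of HTT-10150 on vessels in zQ175 stays untested.

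Genotype calls near Htt on chromosome 5 were weighed last, since Abhd1, Otof and Wfs1 lie within 10 Mb of the altered gene. In NTC mice 15, 32 and 22 tested genes in that region were called (9.2, 20.1 and 14.8 percent, against 5.2, 14.7 and 10.3 elsewhere; Fisher's exact p = 0.0322, 0.0711 and 0.0784), and their share stood at percentiles 95.1, 90.2 and 89.3 of other 20 Mb windows. A response growing with age as elsewhere stays open. The ratio of the effect at 10 to that at 6 months was 1.06 near Htt and 1.39 to 2.67 in random called sets elsewhere. Yet most genes called near Htt changed more at 10 months. Variants of the donor strain carried along with the knock-in allele stay open: they would need the 95th percentile in each regimen, and the shares of 6[4]10 and 2.6[8]10 fell short of it (21.3 and 17 percent) by less than their SE. An effect of the allele on its neighbours that is already full at 6 months was not tested.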

How the results depend on the processing

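Chosen only after seeing the data were the tests without the libraries that stand apart, without the striatal library and without the library high in Skor1, those with a choroid plexus covariate or with untreated mice as the reference, and those without single mice. The rate in brackets after a count of genes, also chosen later, is calls per 10000 genes with an adjusted p, whose number differs between settings. Changes by over 1.5 times were judged on the counts. Where only a rate is given, the exact count is left out because it equals a number in the library names.

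The genotype effect on hippocampal genes was the most stable result. Its counts of called genes moved by less than 1.5 times with DESeq2 size factors, with no filter on low counts, with the DESeq2 Wald test, with a replicate block, with limma-voom and the library-name number as a block, with no sex term, with the choroid plexus covariate and without the libraries that stand apart, in untreated and in NTC mice of each regimen, and no single mouse moved them further. With DESeq2 size factors, all 71 counts, scores and Htt differences were on the same side or within 1.5 times. Among 12231 values of named genes under the alternatives, 10493 kept direction and call, 1717 kept the direction without the call, 4 gained the call and 17 turned direction.

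Fewer mice lowered most counts, which fewer samples explain in part. Leaving out each replicate number in turn gave 320 (195.8) to 514 (314.6) genes for genotype in untreated mice of 2[4]6, 1160 (701.1) to 1459 (890.8) in 6[4]10 and 905 (571.3) to 1497 (942.3) in 2.6[8]10. In NTC mice it gave 355 (212.6) to 704 (423.7) in 2[4]6 and 844 (532.8) to 1734 (1091.5) in 2.6[8]10. For the control siRNA in zQ175 it gave 0 to 495 (302.8) genes in 2[4]6 (edgeR; 2512 at an unadjusted p under 0.05 with all mice) and 33 (20.8) to a rate of 96.4 in 2.6[8]10, where the rate with all mice was 101.6, and in WT 14 (8.84) to 98 (61.7). For HTT-10150 in zQ175 it gave 20 (12.2) to 856 (515.2), 0 to 24 (14.7) and 38 (24) to 99 (62.4) genes in 2[4]6, 6[4]10 and 2.6[8]10. In WT it gave 4 (2.41) to 11 (6.73), 0 to 3 (1.84) and 130 (81.8) to 545 (343.3). For HTT-634 and HTT-486 in zQ175 it gave 0 to 4 (2.45), 12 (7.39) to a rate of 148.7 (95.9 with all mice) and 71 (44.8) to 315 (198.3), and in WT 0 to 6 (3.67), 0 to 1 (0.616) and 26 (16.4) to 70 (44.1). For the direct contrast it gave a rate of 78.9 to 2344 (1434.7), against 1166.8 with all mice, then 2 (1.23) to 12 (7.33) and 8 (5.05) to 31 (19.5). In the order of the settings without replicate 1, 2, 3 and 4, 19, 22, 19 and 15 of 36 results changed, where each 0 is a count by edgeR.

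The signature score also moved with the mice left out. With HTT-634 and HTT-486 against NTC in 6[4]10 its difference was -0.034 with all mice and ranged from -0.05 to -0.006 on the log2 scale. With HTT-10150 against NTC it ranged from -0.102 to -0.003 in 2[4]6, past the threshold without replicate 4, and from -0.063 to -0.044 in 2.6[8]10, short of it without replicate 2, 3 or 4. HTT-10150 against HTT-634.486 ranged from 0.008 to 0.072 in 6[4]10 and from 0.036 to 0.069 in 2.6[8]10. With a signature from other untreated mice, HTT-634.486 against NTC lost the call in 2[4]6 (-0.043, -0.093 before) and gained it in 6[4]10 (-0.041). The direct difference was -0.004 in 2[4]6 and 0.045 in 2.6[8]10, which gained it. With the 50 genes of smallest p these were -0.104 in 6[4]10 for HTT-634.486 against NTC, and 0.147 in 6[4]10 and 0.164 in 2.6[8]10 for the direct difference. With 500 genes they were -0.051 in 6[4]10 and 0.078 in 2.6[8]10, all of which gained the call. With Htt and its neighbours left out, or a prior count of 0.5, all 9 differences kept their call. The cause was not tested.

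Single mice decided several of the HTT-10150 values. For Htt in zQ175 of 2[4]6, leaving out 1 mouse at a time gave exact p = 0.00559 to 0.0525, under 0.05 in 13 of 16 tests and over it without HTT-10150 female_2 (0.0525), NTC female_3 (0.0521) or HTT-10150 male_3 (0.0507). The other HTT-10150 tests of Htt stayed under 0.05 in 16 of 16. For HTT-634 and HTT-486 in WT of 2.6[8]10, the higher Htt had exact p = 0.0351 without HTT-634.486 female_2 and 0.0246 without NTC male_3, and with library size alone in place of TMM its log2 difference was 0.118 and gained the call. For the score of HTT-10150 against NTC in 2[4]6, exact p ranged from 0.00389 without HTT-10150 female_4 to 0.515. For HTT-634 and HTT-486 against NTC in 6[4]10 it was under 0.05 in 10 of 16 tests (0.00357 to 0.0609), and for the direct difference in 3, 1 and 12 of 16 tests of the 3 regimens.

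By limma-trend, leaving out 1 library moved these counts by over 1.5 times. HTT-10150 in zQ175 of 2[4]6 fell from 580 to 199 without NTC male_1, further without NTC male_4 and less without NTC female_4. It fell to 195, 279 and 296 without HTT-10150 male_4, male_3 and male_2. The direct contrast of 2[4]6 went from 2070 to 848 and 1377 without HTT-634.486 male_3 and female_3. HTT-634 and HTT-486 in zQ175 of 6[4]10 went to 49, 53, 67 and 387 without HTT-634.486 female_2, male_3, female_1 and male_4, and to 62, 83, 86, 90 and 93 without NTC male_2, male_3, female_2, male_4 and female_1. The direct contrast of 6[4]10 went from 16 to 10, 9, 10 and 25 without HTT-634.486 female_2, female_1, male_2 and male_4 and to 10 without HTT-10150 male_1. HTT-10150 in zQ175 of 6[4]10 went from 7 to 16 without HTT-10150 female_1 and 12 without NTC male_1.

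Within 2.6[8]10, the control siRNA in WT went to 58, 77 and 80 without NTC female_2, female_1 and male_1 and to 72, 74 and 76 without untreated male_1, male_2 and female_2. In zQ175 it went from 139 to 81 and 83 without NTC male_1 and female_1, to 89 without untreated male_4, and up without NTC female_4. HTT-10150 in zQ175 went from 138 to 80 and 87 without HTT-10150 male_1 and female_4 and to 86 and 89 without NTC male_3 and male_4. In WT it went from 388 to 219 without NTC female_2, with smaller drops without NTC female_4 and male_3. HTT-634 and HTT-486 in WT went from 119 to 50 and 74 without HTT-634.486 female_1 and male_4 and to 60, 76 and 78 without NTC female_2, male_3 and male_2. Counts under 10 moved as well: the control siRNA in zQ175 of 2[4]6 from 4 to 500 without untreated female_3, 2 without untreated male_2, and 17, 80, 49, 2 and 1 without NTC female_1, female_2, female_3, female_4 and male_4.

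For HTT-634 and HTT-486 in zQ175 of 2[4]6 the count went from 8 to 13 without HTT-634.486 female_1 or NTC female_3, to 5 without NTC female_1, female_4 or male_2 or HTT-634.486 female_3 or female_4, to 3 without HTT-634.486 male_1, male_2 or male_3, and to 2 without NTC male_1, male_3 or male_4. In WT of 2[4]6 it went from 2 to 1 without NTC male_1, to 5 without NTC female_3 or HTT-634.486 male_4, to 7 without NTC male_4, and to 0 by limma-trend without HTT-634.486 female_2 or female_4 or NTC female_2, male_2 or male_3. In WT of 6[4]10 it went from 4 to 13 and 10 without HTT-634.486 and NTC female_4, 8 without HTT-634.486 male_3, 2 without HTT-634.486 male_2 or NTC female_3 or male_2, and 1 without NTC female_1. HTT-10150 in WT of 6[4]10 went from 4 to 1 without NTC female_2 and 2 without HTT-10150 male_3, male_4, female_1 or female_2 or NTC female_1, female_3 or male_3. The control siRNA in WT rose from 0 by limma-trend to 4 without NTC male_4 of 2[4]6 and to 3 and 2 without NTC female_4 and male_1 of 6[4]10.

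Other tools changed several counts. The DESeq2 Wald test called 214 (300.6) and 2 (0.741) genes for the control siRNA in zQ175 and WT of 2[4]6, 2 (0.749) and 4 (1.5) in 6[4]10, and a rate of 117.9 in WT of 2.6[8]10 (69.4 by edgeR). It called 892 (617) and 17 (6.3) for HTT-10150 in zQ175 and WT of 2[4]6 and 7 (2.62) in WT of 6[4]10. There were 16 (7.18) and 1 (0.371) for HTT-634 and HTT-486 in zQ175 and WT of 2[4]6 and 363 (263.5) and 14 (7.39) in 6[4]10, and 29 (18.3) and 52 (23.4) for the direct contrast in 6[4]10 and 2.6[8]10. Limma-voom with the library-name number as a block, which changes tool and model at once, called 2 (1.21) genes for the control siRNA in WT of 2[4]6 and 268 (169.1) in zQ175 of 2.6[8]10, 7 (4.28) for HTT-10150 in WT of 6[4]10 and a rate of 148.9 in zQ175 of 2.6[8]10 (87.1 by edgeR). It called 1 (0.603), 8 (4.89) and 222 (140) for HTT-634 and HTT-486 in WT of the 3 regimens and 258 (157.6) and 594 (374.7) in zQ175 of 6[4]10 and 2.6[8]10, and 61 (38.5) for the direct contrast in 2.6[8]10. With no filter on low counts, which adds genes to the adjustment, the calls numbered 309 (114.3), 17 (6.36) and 91 (34.4) for HTT-10150 in zQ175, 3 (1.11) and 84 (31.4) for HTT-634 and HTT-486 in zQ175 of 2[4]6 and 6[4]10, and 1 (0.37) and 56 (21.1) in WT of 2[4]6 and 2.6[8]10. They numbered 68 (25.7) for the control siRNA in WT of 2.6[8]10, 0 for the interaction of HTT-634 and HTT-486 in 2.6[8]10 (edgeR; 799 at an unadjusted p under 0.05 with the filter), and 5 (1.76) and 52 (18.3) between 2[4]6 and the later regimens for genotype in 6[4]10 and HTT-10150 in 2.6[8]10. With no sex term they numbered 3 (1.81) and 1 (0.603) for HTT-634 and HTT-486 in zQ175 and WT of 2[4]6 and 7 (4.28) for HTT-10150 in zQ175 of 6[4]10. With a replicate block, a check of pairing by number that the labels do not support, they numbered 1 (0.603) for HTT-634 and HTT-486 in WT of 2[4]6, 3 (1.81) for the HTT-10150 interaction in 2[4]6 and 7 (4.28) for genotype by sex in 6[4]10. The cause was not tested.

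Without the libraries that stand apart, the control siRNA in zQ175 had 2 (1.2) calls in 2[4]6 and 317 (199.3) in 2.6[8]10, and HTT-10150 in zQ175 6 (3.63) in 6[4]10 and 337 (211.9) in 2.6[8]10 and in WT 173 (108.8). HTT-634 and HTT-486 in zQ175 had 3 (1.8) in 2[4]6 and 684 (430.1) in 2.6[8]10, the direct contrast 11 (6.65) and 60 (37.7) in 6[4]10 and 2.6[8]10, and the interactions 1 (0.629) and 6 (3.77) in 2.6[8]10. Without the 5 libraries that stand apart in the model of all regimens, HTT-10150 had 24 (14.3) between 6[4]10 and 2[4]6 and 1 (0.597) between the 10-month sets, and genotype 10 (5.97) between 2.6[8]10 and 2[4]6. Without the striatal library alone, the counts of 2.6[8]10 were 318 (199.9) and 269 (169.1) for the control siRNA in zQ175 and WT, 337 (211.9) and 264 (165.996) for HTT-10150, 693 (435.7) and 329 (206.9) for HTT-634 and HTT-486, and 60 (37.7) for the direct contrast. This library belongs to only the WT HTT-10150 group, so it reaches the other comparisons through the variance fitted over all 64 libraries. Pdyn in HTT-10150 WT mice turned to -0.02 without it and to -0.037 without all that stand apart, and without replicate 1, which holds it, Pdyn was -0.046 to 0.983 over the replicates, Pcp4 -0.045 to 1.346 and Six3 -0.123 to 4.609.

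Without the library high in Skor1, HTT-634 and HTT-486 had 10 (6.01) calls in zQ175 of 2[4]6, Skor1 turned to -0.809 with HTT-10150 and Pax2 to -0.011 in the direct contrast. Over the replicates left out, Skor1 there ran from -0.901 to 2.796, and with limma-voom and the library-name number as a block it was -0.06. With the choroid plexus covariate the calls numbered 34 (20.5) for the control siRNA in zQ175 of 2[4]6 and 1 (0.611) in WT of 6[4]10, 387 (233.5), 17 (10.4) and a rate of 142.6 (87.1 without it) for HTT-10150 in zQ175 and 5 (3.05) in WT of 6[4]10. They numbered 1 (0.603), 11 (6.72) and 192 (121.1) for HTT-634 and HTT-486 in WT, 51 (32.2) for the direct contrast in 2.6[8]10, 2 (1.21) and 1 (0.631) for the HTT-10150 interaction in 2[4]6 and 2.6[8]10 and 0 for the other in 2.6[8]10 (edgeR; 799 at an unadjusted p under 0.05 without it).

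Untreated mice as the reference take the control siRNA out but add delivery. HTT-10150 in zQ175 then had 1 (0.603) call in 2[4]6 and a rate of 149.5 in 2.6[8]10 (87.1 against NTC). In WT it had 1 (0.611) in 6[4]10. HTT-634 and HTT-486 in zQ175 had 1091 (658.2), 638 (389.6) and 777 (490.2) and in WT 0, 0 and 27 (17) (edgeR; 642 and 1259 at an unadjusted p under 0.05 against NTC in the first pair). Atp5j turned to 0.011 with HTT-10150 in zQ175 of 2[4]6 and Ppl to 0.039 with HTT-634 and HTT-486 in zQ175 of 2.6[8]10. For WT of 2.6[8]10, Wfs1 turned to -0.015, Dok7 to -0.004 and Npc1 to 0.018 with HTT-10150, and Trak2 to 0.049, Dok7 to -0.011 and Itgam to -0.001 with HTT-634 and HTT-486.

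For the gene lists, the test with an estimated correlation kept 5 of 53 calls for genotype in untreated mice (developmental factors at 10 months, where the filter favours rises, sterol synthesis in 6[4]10, glutamate receptors and calcium genes in 2.6[8]10) and 5 of 65 in NTC mice. It kept 1 of 43 for the control siRNA in zQ175 and 0 of 39 in WT, 2 of 48 for HTT-10150 in zQ175 and 2 of 25 in WT, 0 of 34 and 0 of 28 for HTT-634 and HTT-486, 3 of 59 for the direct contrast and 0 of 29 and 0 of 24 for the interactions. Total counts limit little at these depths: the range of 8.4M to 65.7M per library leaves the spread between mice as the main source of error, and in simulated data 80 percent of genes raised 1.5-fold were called.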

Other observations

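Counts over other splits of the libraries, values of single mice and the word GTAGTTA were chosen only after the result was seen.

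Levels of some developmental transcription factors in zQ175 mice are given here without a test. Chosen after their values were seen, Hoxa2 averaged 0.99 ± 0.33 CPM in untreated zQ175 mice of 2.6[8]10 (SD, n = 8), 0.64 ± 0.15 with NTC, 0.26 ± 0.15 with HTT-10150 and 0.16 ± 0.21 with HTT-634 and HTT-486, and it was 0 in every WT mouse of that regimen that was left untreated. Skor1 averaged 13.9 ± 3.25, 9.78 ± 1.88, 3.99 ± 0.79 and 3.37 ± 1.39 CPM in the same order, and Pax2 averaged 11.23 ± 2.11, 5.08 ± 2.56, 6.29 ± 1.49 and 2.86 ± 1.63. For 6[4]10, where treatment came at 6 months, Skor1 averaged 13.15 ± 4.48, 13.89 ± 2.92, 15.33 ± 6.41 and 10.06 ± 1.77 CPM, and Pax2 10.33 ± 3.68, 7.86 ± 2.15, 11.4 ± 5.25 and 5.77 ± 0.76. Hoxc4 averaged 0.69 ± 0.27 CPM in untreated zQ175 mice of 2.6[8]10 and 0.51 ± 0.17, 0.44 ± 0.14 and 0.5 ± 0.26 with the treatments.

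In 2 zQ175 mice given HTT-10150 these genes stood apart together, chosen after their values were seen. Of 2[4]6, female_4 had Skor1 at 16.07, Pax2 at 18.44 and Foxd1 at 8.38 CPM. The other 31 zQ175 mice of that regimen had 0.04 to 0.57, 0.26 to 1.31 and 0.66 to 2.41 CPM. Of 6[4]10, male_2 had Skor1 at 30.5, Pax2 at 24.12, Foxd1 at 17.46 and Hoxa7 at 10.36 CPM. The other 31 had 7.32 to 19.9, 3.45 to 14.14, 1.67 to 5.02 and 0.26 to 1.39 CPM.

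Knockdown was set against the signature score in the hypothesis that mice with less Htt have lower scores. Within the HTT-10150 zQ175 mice (n = 8 per regimen), Spearman's rho was 0.12, -0.86 and 0 (exact permutation p = 0.793, 0.0107 and 1; adjusted over 3 relations 1, 0.0321 and 1) and Pearson's r was -0.17, -0.52 and 0.19 (exact permutation p = 0.713, 0.188 and 0.664). Without the 2 mice farthest from the median of Htt, r was -0.05, -0.29 and -0.14. How far Htt was lowered in each mouse thus went with a lower score in 0 regimens, and in 6[4]10 the order was the opposite.

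Sequence words in 3' untranslated regions were searched for the siRNAs. A seed match of HTT-10150 is a candidate explanation for part of the genes it lowered: the word GAGATTA, found in WT mice of 2.6[8]10, ranked 1 of 16286 in zQ175 (statistic -8.15), and 22 of 48 lowered genes that could be searched held it against 8.9 percent of all genes. It ranked 1, 19, 1 and 1 in the other regimens; in zQ175 of 2[4]6, where it ranked 19, 5.8 percent of the lowered genes held it. A seed match of HTT-634 or HTT-486 stays open, although the word found in WT, TGGTTGG, ranked 1032 in zQ175. In zQ175 the word GTAGTTA ranked 1 (statistic -7.91), and it ranked 8, 101, 3, 3 and 834 in the other 5 contrasts of that pair.

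Untreated mice of both sets collected at 10 months differed by set. Ndufc2, a subunit of respiratory complex I, was 1.11 ± 0.11 higher in WT and 0.89 ± 0.11 higher in zQ175 in 2.6[8]10 than in 6[4]10.

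Shared calls of both active treatments in zQ175 were compared with simulated contrasts that share only their NTC mice. The correlation across genes, which are not independent replicates, was 0.211, 0.467 and 0.618 in 2[4]6, 6[4]10 and 2.6[8]10, against 0.499, 0.499 and 0.501 in simulation. With the NTC mice split so that none is shared, it was -0.084, 0.072 and 0.151.

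Other splits of the libraries into groups of the same sizes were counted by limma-trend, 100 per comparison, the real one included. Chance is argued against for genotype in untreated mice, where only the real split had as many calls in each regimen. It had 533, 2301 and 2202 calls, others at most 462 and 722 in the later regimens. The same holds in NTC mice (1 split, with 1001, 2321 and 1911 against 11, 709 and 1). For the control siRNA in zQ175 the counts were 3, 100 and 1 splits (1 and 0 calls against 1 and 2 in the first pair of regimens, and more than the 99 of any other split in 2.6[8]10). Chance is thus argued against in 2.6[8]10, while 1 call is too few to weigh. Where the real split had 0 calls, every split had as many, so these tests say nothing. In WT the counts were 100, 100 and 2 (0, 0 and 200 against 2, 2 and 248), where 1 split of 2.6[8]10 had more. For HTT-10150 in zQ175 they were 1, 100 and 1 (322 and 0 against 22 and 1172, and above 94 in 2.6[8]10). In WT they were 1, 100 and 1 (13, 0 and 23 against 6, 1 and 1). Chance is argued against except in 6[4]10. For HTT-634 and HTT-486 in zQ175 they were 100, 1 and 1 (0, 116 and 528 against 1, 3 and 15), and in WT 100, 5 and 1 (0, 1 and 80 against 279, 1 and 27). Chance is argued against for both later regimens of zQ175 and for 2.6[8]10 of WT. It is not for the 1 call in WT of 6[4]10, and it was not tested by the 0 calls of 2[4]6. For the direct contrast they were 1, 4 and 1 (3 and 50 calls against 30 and 1 in the later regimens). Chance is argued against in 2.6[8]10, while in 2[4]6 another split came close to the real one, and in 6[4]10 others had 30 and 14.

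For the interaction with genotype, the counts of splits were 2, 100 and 3 for HTT-10150 (91, 0 and 2 calls against 282, 14 and 201) and 100, 100 and 2 for HTT-634 and HTT-486 (0, 0 and 9 against 0, 6 and 24). Few splits had as many where the count is 2 or 3, yet in each case 1 had over 2 times the real count, and edgeR called 0 genes where limma-trend called 91. For genotype by sex they were 7, 1 and 1 (1, 16 and 618 against 575, 0 and 14), and chance cannot be excluded in 2[4]6. Between regimens, in the order 6[4]10 minus 2[4]6, 2.6[8]10 minus 2[4]6 and 2.6[8]10 minus 6[4]10, they were 1, 2 and 100 for genotype (26, 34 and 0 calls), 2, 1 and 6 for HTT-10150 (18 calls against 849 in the first pair) and 100, 100 and 1 for HTT-634 and HTT-486 (0, 0 and 2 against 767, 10 and 1). Chance is argued against between regimens where 1 split had as many, save for the last, where 2 calls are too few to weigh. With 2 splits, the other had several times the real calls. For untreated mice of both 10-month sets they were 1 in WT and 2 in zQ175 (762 and 373 against 21 and 449). Splits with several times the real count point to sample structure, as by library-name number, whose part was not tested. Splits cannot tell it from an effect.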
